A study of Homo sapiens with 12 samples.

How the data were processed

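The 12 libraries come from T cells of 3 individuals, with 1 library for each individual, tissue (bone marrow or lymph node) and CD69 status. Per the labels' protocols, total RNA was taken from untreated primary cells, poly-A RNA was enriched, libraries were made with a TruSeq RNA kit and sequenced on an Illumina instrument. Each deposited table holds raw read counts per gene symbol for 1 library, as the authors made them, with no normalization. The submitters' processing notes name bcl2fastq 1.8.4, TopHat, Cufflinks and DESeq without roles, and a mouse genome build, although the gene symbols in the files are human. The counter, its settings and the annotation are not given in the sources used here. The names of the deposited tables call the counts stranded, and the labels do not say whether the kit marked strand. A library without strand marks that is counted by strand loses the reads of the other strand, and overlapping antisense genes then share reads, so no antisense gene is named. No coordinates are given, because the build is in doubt.

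Besides genes, each table has summary lines that name no gene, and these were kept out of library sizes and tests. Reads outside annotated genes were 50.1 to 80.7% of the reads aligned to a single place, by library. Of 25559 gene symbols per table, 20013 matched a current RefSeq symbol, 2393 an older synonym and 3153 neither, and the files' own symbols are used throughout. Genes of X inactivation and of the Y chromosome were left out of every table, which kept 25447 symbols. Genes with near-identical copies, such as HBA1 and HBA2 or XCL1 and XCL2, can share reads, so their single values are uncertain. Depth ranged from 4395877 to 14764446 counts on genes, and at 3 libraries per group the spread between individuals sets the precision. Replicates of every group differed by more than sampling noise (chi-square per degree of freedom of at least 21.2 over genes).

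The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) in a single fit of the 4 groups with TMM factors, 8 residual degrees of freedom and no covariate. The filterByExpr filter by group kept 14015 genes and removed 11432. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over these genes. Standard errors are the fold change over the root of the F statistic, and CPM values use TMM-scaled library sizes. Contrasts were lymph node minus bone marrow in CD69+ and in CD69− cells, CD69+ minus CD69− in each tissue, and the difference of the last 2. Common biological coefficients of variation were 0.307 without and 0.179 with the individual as a block.

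The labels put the same individuals in all groups, so the individual pairs the libraries. As a check, deviations from the group means correlated between libraries of 1 individual (18 pairs, lowest r 0.181, median 0.346), and all 12 libraries paired best with their own individual. Between individuals the median was -0.186 and the highest -0.0011. Centring each group on its own mean pushes these values below 0, so they are no separate evidence. The block was fixed as an alternative, and its value is printed beside a result where it changes a call or moves a count by more than 1.5 times. It leaves 6 residual degrees of freedom.

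Gene lists (34, of which 31 had at least 3 tested genes) covered T cell states, signalling and metabolic pathways and markers of other cell types. They were written from general knowledge, and none was taken from these samples. The list called egress, or egress and recirculation, joins genes of egress with genes known as lower in resident memory T cells. It therefore does not measure egress alone. No source was recorded for single genes, so the residency and egress lists may hold genes first found by comparing CD69+ with CD69− cells. Their shift by CD69 would then be no separate evidence on residency or egress. Every list was tested by limma's camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes. The tests were two-sided, adjusted over the lists of a contrast, and repeated with an estimated correlation and by fry. With an estimated correlation 4 calls held: NF-kB genes and monocyte and granulocyte genes between tissues in CD69+ cells, and egress genes by CD69 in each tissue. Calls per gene are given over all genes and adjusted over the list alone. The list of mitochondrially encoded genes had no gene in the files, and 2 lists of other cells had 2 tested genes each.

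Genes were named by a rule: in each contrast the 10 higher and 10 lower genes with the largest fold change among those called, with a mean of at least 5 CPM in the higher group and the same direction in all 3 individuals; up to 4 members of each list with the lowest adjusted p; always CD69, CD3E, CD8A, CD8B, CD4 and TCF7; and for the difference between tissues the 5 lowest p-values if none passed. Variable segments of antigen receptors, genes whose copy number differs between people, pseudogenes and small RNAs are not named. KLF2, KCNK5, DUSP6, ZNF683 and SLCO3A1 in bone marrow, CXCR6 and GZMB were chosen after their values were seen. Not all genes that meet the rule are named in the text.

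The design, the lists, the rule and the main alternatives were set before the data were examined. The alternatives were the block, DESeq2 1.42.0 with and without it, limma voom (limma 3.58.1) with quality weights, RLE and upper-quartile factors, no filter, a filter at a mean of 5 CPM, only the 2 groups compared in the fit, library sizes without immunoglobulin, haemoglobin and T cell receptor segment genes, and leaving out each library or individual in turn. edgeR, DESeq2, limma voom and the block were tested on simulated data in which 100 genes were changed by 2-fold and 100 by 4-fold. The simulation took the real mean of each gene and the real library sizes. It used a common spread for all genes, and an individual's effect on a gene was the same in all groups. For the contrasts in CD69+ cells and in lymph node, on 13800 genes, edgeR recovered 78 and 83% of genes changed by 4-fold and 1 and 4% of those changed by 2-fold, with 0 false calls. For those in CD69− cells and in bone marrow, on 13783 genes, it recovered 86 and 85%, and 5 and 4%. With the block, 95 to 100% and 64 to 80% were recovered, with 3.57 to 6.94% false calls. In the data, libraries of the same individual correlated at 0.181 to 0.374 between tissues and at 0.605 to 0.813 within a tissue. The blocked shares for comparisons across tissues, the difference between tissues included, therefore come from a setting unlike the data. In the fits of the data, too, the block gives an individual 1 effect for both tissues. Blocked errors of lymph node against bone marrow may therefore be too small, and the blocked counts of calls too high. For the difference between tissues edgeR recovered 11 and 10% of genes changed by 4-fold without the block and 92 and 95% with it. The camera test found a list of 20 genes shifted by 2-fold in each of the 4 contrasts and called 0 of 33 unchanged lists. The simulated genes varied independently of each other, while in the data the estimated correlation was 0.903 for the erythroid list. The simulation therefore says nothing on false calls of lists whose genes are correlated.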

Results

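Poly-A RNA was sequenced from T cells of the bone marrow and lymph nodes of 3 individuals. In each tissue the cells had been separated by CD69, a surface protein induced on activation and also carried by memory T cells that stay in tissues. This gave 4 groups of 3 libraries. Every individual is in all 4 groups. The series is about memory T cells that reside in lymph nodes. The comparisons therefore asked how lymph node cells differed from bone marrow cells at the same CD69 status, how CD69+ cells differed from CD69− cells within a tissue, and whether that difference depended on the tissue. Counts on genes ranged from 4395877 to 14764446 per library, with group means of 14302495 in bone marrow CD69−, 7877387 in bone marrow CD69+, 8634160 in lymph node CD69− and 6272926 in lymph node CD69+ libraries.

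The labels name no T cell subset. CD8A and CD8B, the chains of the CD8 coreceptor, had group means of 851 to 1068 and of 156 to 168 CPM (counts scaled to the library size), against 3.54 to 6.27 CPM for CD4. None of CD3E, CD8A, CD8B and CD4 passed the test in any of the 4 comparisons. With the individual as a block, CD3E alone did, between tissues in CD69− cells (log2 fold change -0.47 ± 0.18, adjusted p = 0.0788 without and 0.0261 with the block). The first principal component of log2 CPM held 47.0% of the variance and parted lymph node from bone marrow libraries. The fourth component, with 7.28%, parted CD69+ from CD69− libraries.

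**Figure D1:**
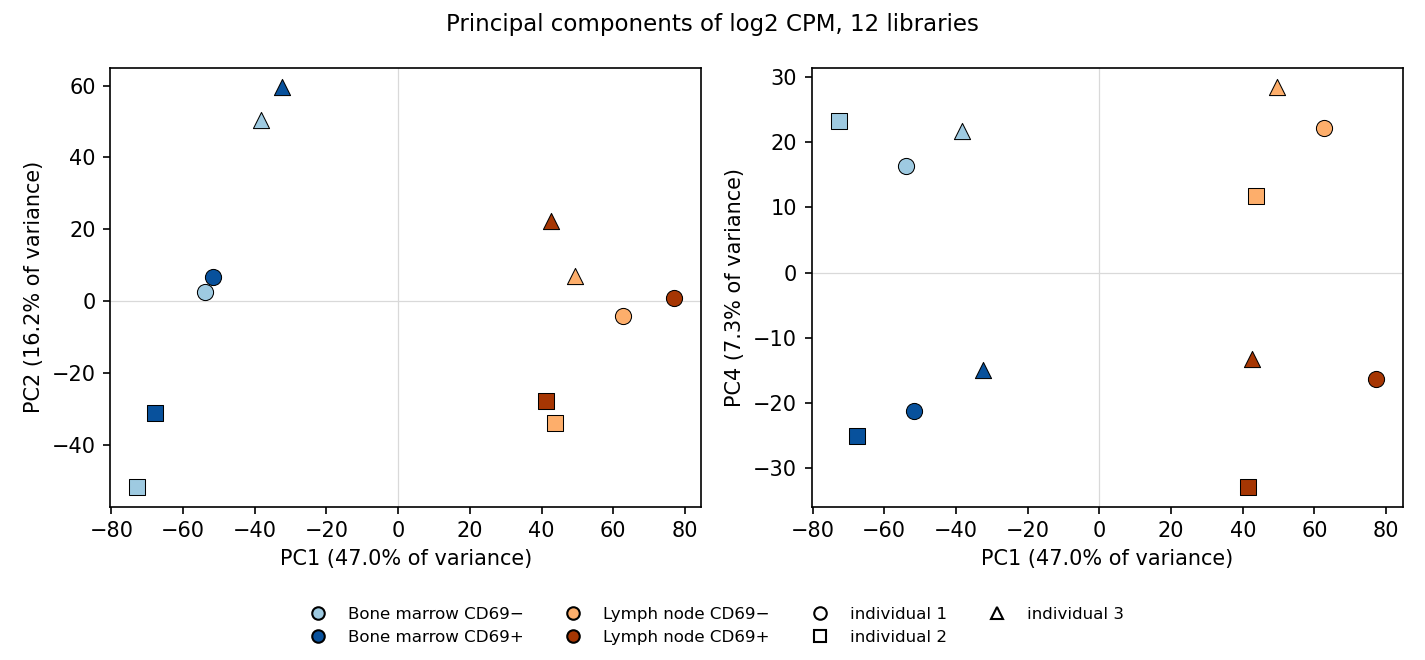
Principal components of log2 CPM for the 12 libraries. The left panel plots component 1 (47.0% of the variance) against component 2 (16.2%) and the right panel component 1 against component 4 (7.28%). Each point is a library coloured by group, and the marker shape gives the individual. Lymph node libraries lie to the right of bone marrow libraries, and CD69+ libraries lie below CD69− libraries on component 4.

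The CD69 transcript averaged 467 ± 129 CPM (SD, n = 3) in bone marrow CD69− cells, 1492 ± 145 in bone marrow CD69+ cells, 1991 ± 1033 in lymph node CD69− cells and 3417 ± 1852 in lymph node CD69+ cells. It was 2.09 ± 0.50 (log2, SE) higher in lymph node than in bone marrow CD69− cells (adjusted p = 0.0137). The difference between CD69+ and CD69− cells was 1.68 ± 0.49 in bone marrow (adjusted p = 0.337, 0.0505 with the individual as a block) and 0.78 ± 0.48 in lymph node (adjusted p = 1). Fold changes from here on are log2 ± SE with n = 3 per group.

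**Figure D2:**
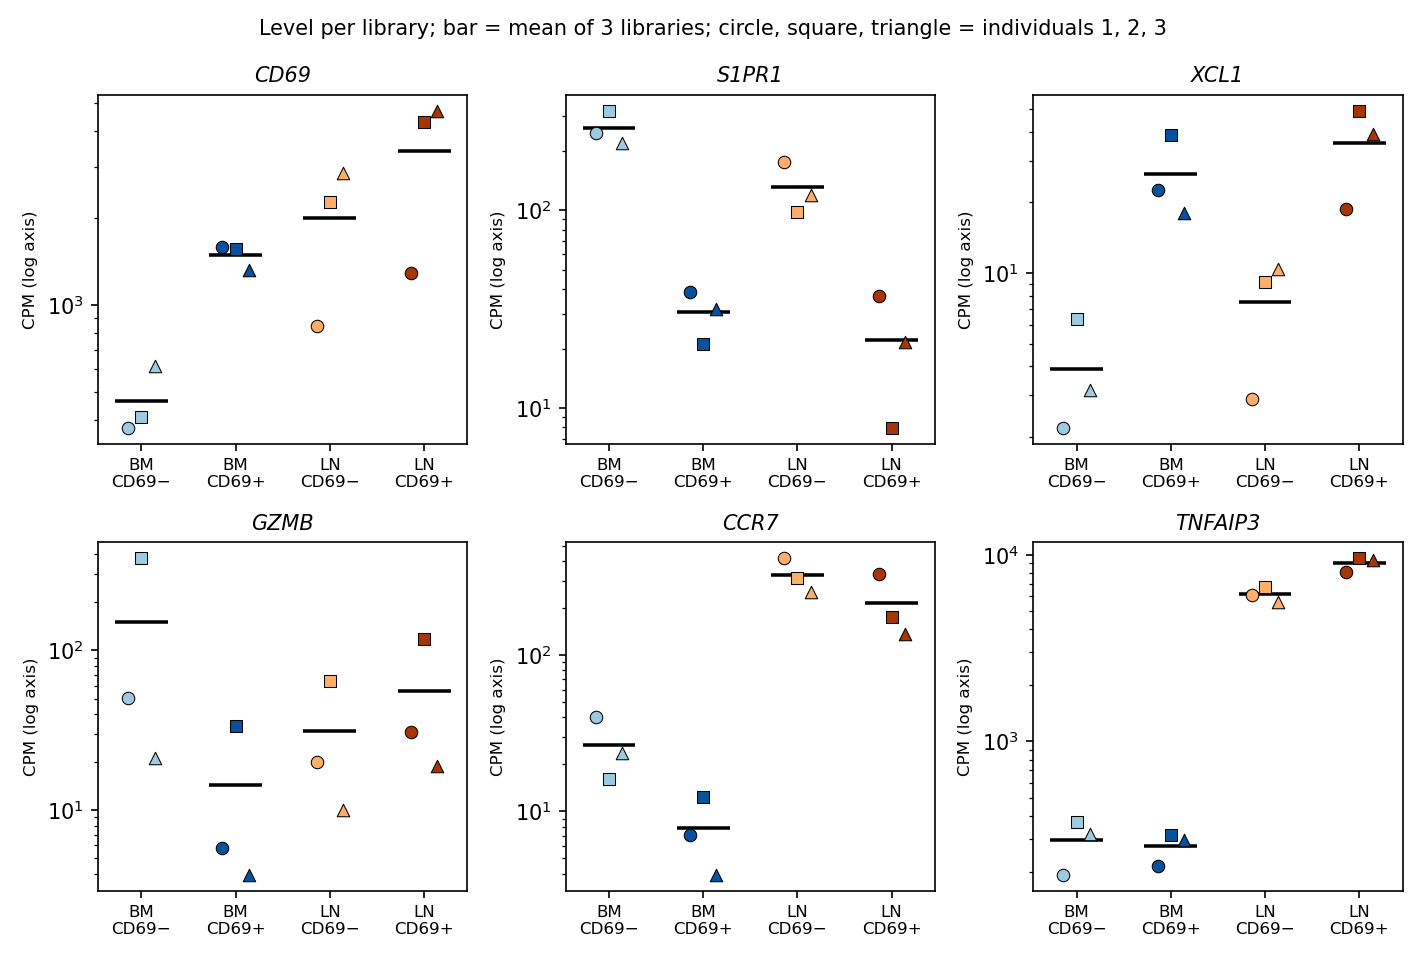
Levels of 6 genes in each of the 12 libraries, in CPM on a log axis. The horizontal bar is the mean of a group of 3 and the marker shape gives the individual. S1PR1 was lower and XCL1 higher in CD69+ than in CD69− libraries of both tissues in every individual. CCR7 and TNFAIP3 were higher in lymph node libraries. GZMB was lower in CD69+ than in CD69− libraries of bone marrow and higher in those of lymph node, and this gene was chosen after its values were seen.

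Among CD69+ cells, lymph node libraries had higher levels of immediate early and NF-kB pathway transcripts than bone marrow libraries. TNFAIP3, which encodes the NF-kB inhibitor A20, averaged 9040 ± 819 CPM (SD) in lymph node and 275 ± 52.8 in bone marrow, a log2 fold change of 5.04 ± 0.29 (adjusted p = 2.31e-05). The nuclear receptor genes NR4A2 and NR4A3, induced by T cell receptor signals, rose by 3.73 ± 0.24 and 5.07 ± 0.71. DUSP4, a phosphatase of MAP kinases, rose by 5.39 ± 0.54. Of 25 immediate early and activation genes, 15 were called higher and 0 lower (16 and 0 adjusted over the list alone). The camera adjusted p of this list was 5.35e-11, and its adjusted p = 0.0872 with an estimated correlation. Of 16 NF-kB genes, 12 were called higher, also 12 adjusted over the list alone, among them REL (3.19 ± 0.38), BIRC3 (2.80 ± 0.25) and NFKBIA (2.96 ± 0.39). The camera adjusted p was 2.19e-08, with adjusted p = 0.0311 with an estimated correlation and 0.054 when the individual was a block as well. In the same libraries the share of reads outside annotated genes was 75.8 ± 5.55% (SD) in lymph node and 63.7 ± 7.94% in bone marrow.

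The list of stem-like and quiescent memory genes was also higher as a whole in lymph node CD69+ cells. CCR7, the chemokine receptor that guides T cells into lymph nodes, rose by 4.74 ± 0.52 (adjusted p = 3.11e-04). GPR183, a receptor that positions cells within lymphoid tissue, rose by 2.92 ± 0.25 and the transcription factors LEF1 and BACH2 by 2.85 ± 0.32 and 2.28 ± 0.45. Of 20 stem-like and quiescent memory genes, 9 were called higher and 0 lower (10 and 2 adjusted over the list alone), with a camera adjusted p of 1.34e-04 and an adjusted p = 0.218 with an estimated correlation. TCF7, a transcription factor of stem-like T cells, had a fold change of 0.64 ± 0.29 (adjusted p = 0.156, 0.044 with the block). The Notch and Wnt list had 7 of 14 genes called higher (8 adjusted over the list alone), led by AXIN2, a Wnt target (3.13 ± 0.31), and DTX1, a Notch target (3.71 ± 0.76). Its camera adjusted p was 1.34e-04, with an adjusted p = 0.0673 with an estimated correlation. The TGF-beta list had 7 of 14 genes called higher, also 7 adjusted over the list alone, with a camera adjusted p of 0.00894 and an adjusted p = 0.277 with an estimated correlation. Its leading members PMEPA1 (5.21 ± 0.78), SKIL (2.73 ± 0.32) and SKI (2.49 ± 0.42) are known as restraints on TGF-beta signalling. In the blocked fit the stem-like list had 11 genes called higher and 2 lower (13 and 2 adjusted over the list alone) and the TGF-beta list 7 and 2, also 7 and 2 adjusted over the list alone.

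The list of CD4 T cell genes was higher as a whole too. CTLA4 rose by 4.03 ± 0.33, IL2RA by 3.58 ± 0.49, ICOS by 2.40 ± 0.19 and TNFRSF4 by 2.32 ± 0.43, while CD4 itself had a fold change of 0.45 ± 0.71 (adjusted p = 0.695). Of the 11 genes of the CD4 T cell list, 6 were called higher and 0 lower (7 and 0 adjusted over the list alone), with a camera adjusted p of 6.15e-04 and an adjusted p = 0.0772 with an estimated correlation. The genes with the greatest rises included GEM, a small GTPase (6.61 ± 0.98), LMNA, which encodes lamin A (6.53 ± 0.73), SPDYA (5.74 ± 0.60) and TMEM88 (4.88 ± 0.48). Of 15 genes of the tissue residency list, 5 were called higher and 1 lower (7 and 1 adjusted over the list alone), with a camera adjusted p of 0.0643. ITGA1, the collagen-binding integrin CD49a, was higher by 2.51 ± 0.49 and CRTAM by 2.46 ± 0.53, and the lower member, CXCR6 (-2.05 ± 0.59), was chosen after its values were seen. The blocked fit gave the CD4 T cell list 7 called higher and 1 lower and the residency list 8 and 2, with no change when adjusted over the list alone.

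In the camera test at the preset correlation, the lists of cytotoxic and natural killer (NK)-type genes were each lower in lymph node CD69+ cells. KLRG1, an inhibitory receptor of effector cells, was at -1.25 ± 0.16, the activating receptor NCR3 at -2.39 ± 0.59 and the signalling adaptor TYROBP at -3.01 ± 0.46. Also lower were the granzyme gene GZMA (-1.39 ± 0.39) and the death ligand FASLG (-1.88 ± 0.46). The NK-type list had 4 of 16 genes called lower (6 adjusted over the list alone), with a camera adjusted p of 0.0178 and an adjusted p = 0.277 with an estimated correlation. The cytotoxic list had 3 of 16 called lower, also 3 adjusted over the list alone, with a camera adjusted p of 0.0463 and an adjusted p = 0.809 with an estimated correlation. By fry the adjusted p was 0.254 for the cytotoxic list, which did not pass, and 0.00286 for the NK-type list. The NK-type list went both ways with the block, with 4 genes called higher and 9 lower (4 and 10 adjusted over the list alone), and the cytotoxic list had 1 called higher and 9 lower (1 and 10). The effector transcription factors EOMES (-1.42 ± 0.21) and HOPX (-1.62 ± 0.21) fell, while RUNX3 (1.34 ± 0.24) and BHLHE40 (1.97 ± 0.39) rose. The list of 12 had 3 higher and 2 lower calls (3 and 3 adjusted over the list alone) with a camera adjusted p of 0.832. The egress and recirculation list had 3 of 20 called higher and 2 lower, also 3 and 2 adjusted over the list alone, at a camera adjusted p of 0.957.

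Transcripts of myeloid and erythroid cells were higher in the bone marrow libraries, beside all the groups of genes above. In CD69+ libraries S100A9, a neutrophil and monocyte protein, averaged 562 ± 419 CPM (SD) in bone marrow and 2.21 ± 1.17 in lymph node. LYZ (lysozyme) averaged 351 ± 244 and 9.89 ± 10.1, MPO (myeloperoxidase) 521 ± 795 and 0.605 ± 0.404, and HBB (beta-globin) 1391 ± 1660 and 1.79 ± 1.75. The monocyte and granulocyte list had 10 of 17 genes called lower in lymph node (14 adjusted over the list alone), with a camera adjusted p of 6.59e-08, an adjusted p = 0.0311 with an estimated correlation and 0.111 when the individual was a block as well. The erythroid list had 8 of 9 called lower (9 adjusted over the list alone), with a camera adjusted p of 7.45e-06 and an adjusted p = 0.352 with an estimated correlation. TYROBP and the Fc receptor gene FCGR3A (-2.42 ± 0.75), counted above as NK-type and cytotoxic genes, are expressed by myeloid cells too. The lists of B cells (camera adjusted p 0.234), plasma cells (0.559), megakaryocytes and platelets (0.114) and stroma and endothelium (0.624) did not pass. The collagen gene COL1A1 was higher in lymph node (4.28 ± 1.09, adjusted p = 0.0221).

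Over all 14015 genes tested, 2346 differed between lymph node and bone marrow CD69+ cells, 1395 higher in lymph node and 951 lower, of which 843 and 443 changed by more than 2-fold. With the individual as a block the count was 4701, 2484 higher and 2217 lower, but the errors of this fit between tissues may be too small. Upper-quartile scaling, which moved the median of all genes by -0.11, called 1132 higher and 1401 lower. The count was 1128 without the bone marrow library of individual 1, 1227 without that of individual 2, 1149 without the lymph node library of individual 1, and 1385 with only the 2 groups in the fit. It was 1185 without both bone marrow libraries of individual 2, which had the most haemoglobin counts, an alternative chosen after seeing the data.

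**Figure D3:**
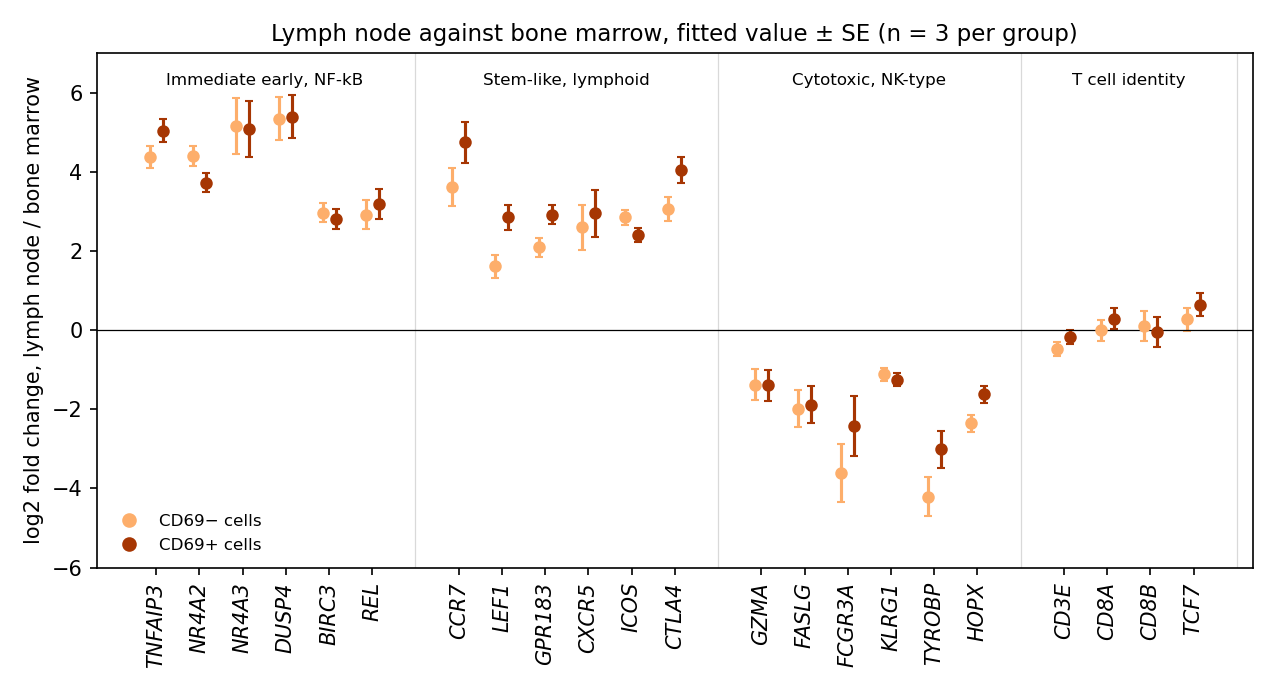
Log2 fold change of lymph node against bone marrow cells for 22 genes, in CD69− cells (light) and CD69+ cells (dark). Points are fitted values and bars are SE (n = 3 per group). The immediate early, NF-kB, stem-like and lymphoid genes lie above 0, the cytotoxic and NK-type genes below 0, and CD3E, CD8A, CD8B and TCF7, none of which passed the test, lie nearest to 0.

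Among CD69− cells the same contrast between tissues gave activation genes of similar size. TNFAIP3 was 4.38 ± 0.28 higher in lymph node (6134 ± 570 against 295 ± 91.8 CPM, SD, adjusted p = 2.44e-05), NR4A2 4.39 ± 0.25, NR4A3 5.16 ± 0.71 and DUSP4 5.34 ± 0.54. Of 25 immediate early genes, 17 were called higher and 0 lower (19 and 0 adjusted over the list alone), with a camera adjusted p of 1.09e-10 and an adjusted p = 0.100 with an estimated correlation. Of 16 NF-kB genes, 10 were called higher (11 adjusted over the list alone), with a camera adjusted p of 2.60e-06 and an adjusted p = 0.0684 with an estimated correlation. The share of reads outside annotated genes was 71.5 ± 1.67% (SD) in these lymph node libraries and 55.0 ± 4.25% in the bone marrow ones.

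The list of follicular helper and lymphoid positioning genes was higher as a whole in lymph node CD69− cells. BCL6, the transcription factor of follicular T cells, rose by 1.73 ± 0.32 and ICOS by 2.85 ± 0.19. Also higher were the cytokine receptor gene IL21R (1.98 ± 0.41), CCR7 (3.62 ± 0.48) and LEF1 (1.61 ± 0.30). The follicular list had 7 of 13 genes called higher and 0 lower (8 and 1 adjusted over the list alone), with a camera adjusted p of 0.00202 and an adjusted p = 0.100 with an estimated correlation. In CD69+ cells 5 of the 13 were called higher and 0 lower (5 and 2 adjusted over the list alone) at a camera adjusted p of 0.0518. The stem-like list had 10 of 20 called higher and 1 lower (11 and 1 adjusted over the list alone, camera adjusted p 2.95e-04, adjusted p = 0.194 with an estimated correlation). The Notch and Wnt list had 7 of 14 called higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p 0.00444, adjusted p = 0.109 with an estimated correlation). The TGF-beta list had 5 of 14 called higher (7 higher and 1 lower adjusted over the list alone) at a camera adjusted p of 0.0565. The CD4 T cell list had 6 of 11 called higher, also 6 adjusted over the list alone, with CTLA4 at 3.05 ± 0.31 and the chemokine receptor CCR4 at 3.00 ± 0.51 (camera adjusted p 2.95e-04, adjusted p = 0.0779 with an estimated correlation). RGS1, a regulator of chemokine receptor signalling that is high in resident memory cells, was 3.71 ± 0.71 higher and ITGA1 3.23 ± 0.52 higher. The residency list, with 6 of 15 called higher and 2 lower (7 and 2 adjusted over the list alone), had a camera adjusted p of 0.0667. Higher and lower calls with the block were 8 and 1 for the follicular list (9 and 1 adjusted over the list alone), 6 and 3 for it in CD69+ cells (also 6 and 3), 11 and 2 for the stem-like list (12 and 2) and 7 and 2 for the TGF-beta list (7 and 3).

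The lists of cytotoxic and NK-type genes were also lower as a whole in lymph node CD69− cells. FGFBP2, a secreted protein of cytotoxic cells, was at -4.33 ± 0.88 and the adhesion receptor GPR56 at -3.36 ± 0.59. The cytotoxic list had 9 of 16 genes called lower and 0 higher, also 9 and 0 adjusted over the list alone, with a camera adjusted p of 4.01e-04 and an adjusted p = 0.557 with an estimated correlation. The NK-type list had 9 of 16 called lower and 0 higher (10 and 1 adjusted over the list alone), with a camera adjusted p of 3.92e-04 and an adjusted p = 0.100 with an estimated correlation. When blocked, the cytotoxic list had 14 called lower and 0 higher and the NK-type list 11 lower and 1 higher, with no change when adjusted over the list alone. The egress list went both ways, with 3 of 20 called higher, among them CCR7, and 5 lower, among them CX3CR1, the fractalkine receptor (-4.82 ± 0.75), and S1PR5 (-2.69 ± 0.51). These counts were also 3 and 5 adjusted over the list alone, at a camera adjusted p of 0.394. So did the effector transcription factors, with RUNX3 higher (1.11 ± 0.23) and 3 of 12 lower, among them TBX21 (-1.14 ± 0.27), also 1 and 3 adjusted over the list alone, at a camera adjusted p of 0.394. With the block that list had 2 higher and 4 lower (2 and 5). Oxidative phosphorylation genes were lower as a list (camera adjusted p 0.0226, adjusted p = 0.641 with an estimated correlation), with 2 of 21 called over all genes, ATP5A1 (-0.50 ± 0.14) and CYC1 (-0.72 ± 0.21), and 0 adjusted over the list alone, against 10 called and 10 over the list alone with the block. With the individual as a block 3 further lists passed, all lower in lymph node: interferon-stimulated genes (camera adjusted p 0.0242, 0.0752 without the block), ribosomal proteins (0.0437, 0.0752 without) and markers of MAIT and gamma-delta T cells (0.0192, 0.0565 without). With an estimated correlation and the block their adjusted p = 0.538, 0.818 and 0.619 in that order.

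The bone marrow CD69− libraries also held the myeloid and erythroid transcripts, with S100A9 at 625 ± 480 CPM (SD) against 2.59 ± 1.02 in lymph node, LYZ at 374 ± 244 against 6.29 ± 2.99 and HBB at 1268 ± 1630 against 1.96 ± 2.50. The monocyte and granulocyte list had 13 of 17 genes called lower in lymph node (14 adjusted over the list alone), with a camera adjusted p of 3.05e-08 and an adjusted p = 0.0511 with an estimated correlation. The erythroid list had 9 of 9 called lower, also 9 adjusted over the list alone, with a camera adjusted p of 2.73e-05 and an adjusted p = 0.452 with an estimated correlation. The lists of B cells (camera adjusted p 0.346, median fold change 0.68) and of stroma and endothelium (0.373, 2.76) did not pass. Neither did those of plasma cells (0.399, -0.71) and of megakaryocytes and platelets (0.0854, -5.24). In all, 3196 of 14015 genes differed, 1742 higher and 1454 lower in lymph node, 962 and 676 of them by more than 2-fold. The block gave 5812 (2899 higher and 2913 lower), where errors between tissues may again be too small. Upper-quartile scaling called 1441 higher and 1882 lower. The count was 1829 without the bone marrow library of individual 1, 1986 without that of individual 2, 1985 and 2005 without the lymph node libraries of individuals 1 and 3. It was 1963 without the bone marrow libraries of individual 2, chosen after seeing the data.

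The 2 tissue comparisons called 1935 genes in common, 1156 higher in lymph node in both, against 173 for independent lists, and 779 lower in both, against 98.7, with 0 in opposite directions. Across the 14015 genes their fold changes had a Pearson r of 0.893 and a Spearman rho of 0.857, where genes are not independent replicates. The 2 comparisons share no library but come from the same individuals. With the block they called 3934 in common, with the same limit on blocked errors between tissues.

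Within bone marrow, the egress list, which also holds genes known as lower in resident memory T cells, was lower as a whole in CD69+ cells. S1PR1, the receptor for the egress signal sphingosine-1-phosphate, averaged 262 ± 51.9 CPM (SD) in CD69− and 30.6 ± 8.92 in CD69+ cells, a fold change of -3.10 ± 0.45 (adjusted p = 0.0286). CX3CR1 fell by 4.27 ± 0.72 on the log2 scale and NPDC1 by 2.81 ± 0.47. Also lower were FAM65B, a RhoA inhibitor in T cells, by 1.58 ± 0.21 and the kinase genes SBK1 and STK38 by 1.73 ± 0.23 and 1.22 ± 0.16. Of 20 egress and recirculation genes, 7 were called lower and 0 higher over all genes and 20 were lower adjusted over the list alone, and with the block 14 were called lower. The list's median fold change was -2.02, its camera adjusted p was 9.43e-42, and its adjusted p = 0.00299 with an estimated correlation. With the block as well, no list called by camera in this comparison had an adjusted p under 0.0441. KLF2, a transcription factor that drives S1PR1 (-1.09 ± 0.29, adjusted p = 0.236), passed with the block (0.0358) and was chosen after its values were seen. In the same libraries the share of reads outside annotated genes was 63.7 ± 7.94% (SD) in CD69+ and 55.0 ± 4.25% in CD69− cells, higher in CD69+ cells in 3 of 3 individuals. Counts on genes averaged 7877387 and 14302495, and were higher in CD69+ cells in 0 of 3.

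The 5 genes called higher in bone marrow CD69+ cells were led by CSF1, the macrophage growth factor, at 68.0 ± 14.3 CPM (SD) against 9.89 ± 2.03 (2.78 ± 0.26, adjusted p = 0.00423). The others were the Notch ligand JAG2 (2.50 ± 0.42), SEMA7A (1.59 ± 0.25), the phosphatase DUSP5 (1.33 ± 0.20) and the bicarbonate transporter SLC4A4 (1.04 ± 0.16). The residency list had 0 of 15 genes called over all genes and 6 higher adjusted over the list alone. Its median was 1.14, its camera adjusted p was 1.17e-10 and its adjusted p = 0.072 with an estimated correlation, or 0.0441 with the block as well. By fry its adjusted p was 0.0617, which did not pass. Among its members RGS1 (3.47 ± 0.70, adjusted p = 0.123) and ITGA1 (2.39 ± 0.51, adjusted p = 0.135) passed with the block (0.00797 and 0.0138). So did KCNK5 (1.43 ± 0.51, 0.0366) and DUSP6 (1.01 ± 0.37, 0.0411) and, in the opposite direction, ZNF683, a transcription factor also known as Hobit (-2.37 ± 1.24, adjusted p = 0.973, 0.0481 with the block), 3 genes chosen after their values were seen. The block thus called 4 members higher and 1 lower (9 and 1 adjusted over the list alone). CD101 (1.40 ± 0.46, adjusted p = 0.503) and IL2 (2.13 ± 0.51, adjusted p = 0.176) did not. The cytokine list had 1 of 19 called, CSF1, and 4 adjusted over the list alone (camera adjusted p 9.96e-06, adjusted p = 0.190 with an estimated correlation). The chemokine genes XCL1 (2.76 ± 0.54, adjusted p = 0.101) and CCL3 (2.35 ± 0.69, adjusted p = 0.328) passed with the block (0.00438 and 0.0431). The immediate early list had 0 of 25 called and 4 higher adjusted over the list alone, with a median of 0.50, a camera adjusted p of 1.40e-07 and an adjusted p = 0.212 with an estimated correlation. With the block the cytokine list had 4 called higher (7 adjusted over the list alone) and the immediate early list 0 (15).

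The cytotoxic list was lower in bone marrow CD69+ cells, with 0 of 16 genes called and 4 adjusted over the list alone (camera adjusted p 0.00107, adjusted p = 0.526 with an estimated correlation). GNLY, the pore-forming protein granulysin (-3.79 ± 0.86, adjusted p = 0.163), and FGFBP2 (-4.92 ± 0.91, adjusted p = 0.082) passed with the block (0.00157 and 0.00221). The stem-like list was lower with 1 of 20 called, LEF1 (-2.04 ± 0.31), and 1 higher and 3 lower adjusted over the list alone (camera adjusted p 0.010, adjusted p = 0.404 with an estimated correlation). The inhibitory receptor list was higher with 0 of 13 called and 3 adjusted over the list alone (camera adjusted p 0.0138, adjusted p = 0.343 with an estimated correlation). Its members CD160 (3.16 ± 0.79, adjusted p = 0.209) and TOX2 (2.73 ± 0.61, adjusted p = 0.152) passed with the block (0.0014 and 0.0138). The follicular list was higher with 0 of 13 called and 3 higher and 1 lower adjusted over the list alone (camera adjusted p 0.00328, adjusted p = 0.190 with an estimated correlation). The remaining lists past the camera test had at most 1 gene called. Notch and Wnt genes were lower at 0.0138 (adjusted p = 0.212 with an estimated correlation, and 0.0568 with the block, which ends the call). Cell cycle genes were lower at 0.00275 (adjusted p = 0.609 with an estimated correlation). Ribosomal protein genes were lower at 9.07e-08 with a median of -0.20 (adjusted p = 0.546 with an estimated correlation). Oxidative phosphorylation genes were lower at 9.78e-05 with a median of -0.20 (adjusted p = 0.404 with an estimated correlation, 0.0441 with the block as well). MAIT and gamma-delta markers were higher at 0.0152 (adjusted p = 0.586 with an estimated correlation). Adjusted over the list alone, 2 of the Notch and Wnt genes and 0 of the genes of the other 4 lists were called lower or higher. With the block, 6 cytotoxic genes were called lower and 0 higher (8 and 1 adjusted over the list alone), 3 stem-like genes lower (6 lower and 1 higher), 2 inhibitory receptors higher (4 higher and 2 lower), 1 follicular gene higher (4 higher and 1 lower), 2 Notch and Wnt genes lower (3) and 0 oxidative phosphorylation genes (1 lower).

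In all, 29 of 14015 genes differed between CD69+ and CD69− cells in bone marrow, 5 higher and 24 lower, with 803 at an unadjusted p under 0.05. With the block the count was 225 (123 lower and the others higher), with DESeq2 200 and with limma voom 86. It was 0 with only the 2 groups in the fit and 0 without the bone marrow libraries of individual 2, chosen after seeing the data. Leaving out all libraries of individual 1, 2 or 3 also gave 0 each time. The 17 named calls lost without the bone marrow libraries of individual 2 had a median absolute log2 fold change of 1.99 there, against 2.29. With a single bone marrow library left out it was 2, 16 and 17 for the CD69− libraries of individuals 1, 2 and 3 and 1, 1 and 4 for the CD69+ libraries. The numbers in the library titles run separately for CD69+ and CD69− libraries, so a batch that follows them cannot be told apart from CD69 status in either tissue.

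**Figure D4:**
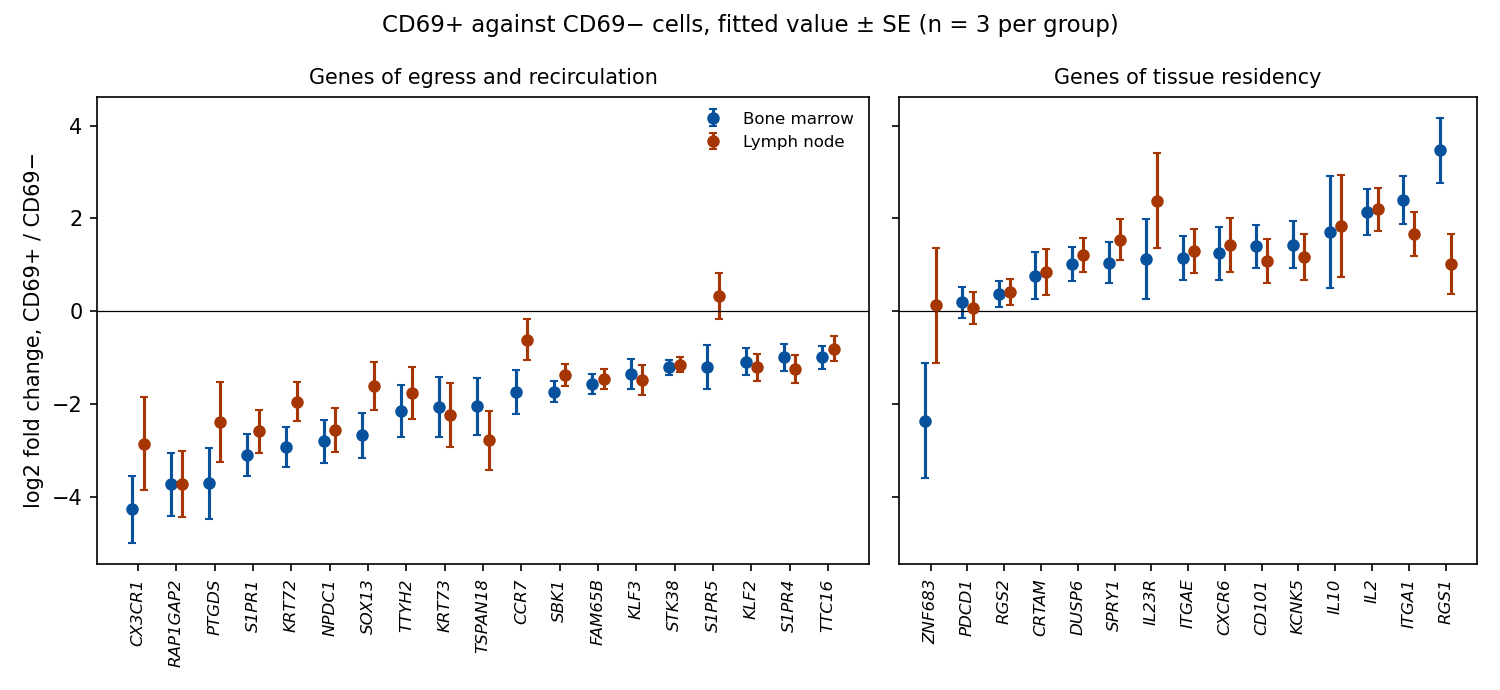
Log2 fold change of CD69+ against CD69− cells in bone marrow (blue) and lymph node (red). The left panel holds the egress list, with 1 of its 20 tested genes not drawn. This list includes genes known as lower in resident memory T cells. The right panel holds the 15 tested genes of tissue residency. Points are fitted values and bars are SE (n = 3 per group). The medians of all 20 genes of the left list are -2.02 in bone marrow and -1.68 in lymph node, and those of the right list 1.14 and 1.21.

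Within lymph nodes the egress list was also lower as a whole in CD69+ cells. S1PR1 averaged 131 ± 40.1 CPM (SD) in CD69− and 22.2 ± 14.5 in CD69+ cells, a fold change of -2.59 ± 0.46 (adjusted p = 0.157, 0.0165 with the block). STK38 (-1.16 ± 0.16, adjusted p = 0.0516), FAM65B (-1.46 ± 0.21, 0.0618) and SBK1 (-1.37 ± 0.24, 0.157) also passed with the block (0.0113, 0.0121 and 0.0447). Of the 20 egress genes, 0 were called over all genes and 18 were lower adjusted over the list alone, and with the block 9 were called lower. The median was -1.68, the camera adjusted p 1.26e-33 and the adjusted p = 0.00638 with an estimated correlation. With the block as well, no list called by camera in this comparison had an adjusted p under 0.0447. The share of reads outside annotated genes was 75.8 ± 5.55% (SD) in these CD69+ and 71.5 ± 1.67% in the CD69− libraries, higher in CD69+ cells in 3 of 3 individuals. Counts on genes averaged 6272926 and 8634160, and were higher in CD69+ cells in 0 of 3.

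The residency list was higher in lymph node CD69+ cells, with 0 of 15 genes called and 4 adjusted over the list alone. Its median was 1.21, its camera adjusted p 2.39e-10 and its adjusted p = 0.0571 with an estimated correlation, or 0.0447 with the block as well. By fry its adjusted p was 0.0609, which did not pass. Its members IL2 (2.19 ± 0.46, adjusted p = 0.237), ITGA1 (1.67 ± 0.48, 0.532) and ITGAE, the integrin CD103 (1.29 ± 0.47, 0.803), did not pass with or without the block. NK-type receptors were higher as a list with 0 of 16 called, over all genes or adjusted over the list alone (camera adjusted p 6.42e-06, adjusted p = 0.0571 with an estimated correlation, 0.0447 with the block as well). Its member CD160 (2.28 ± 0.83, adjusted p = 0.808) passed with the block (0.0133). Cytokine genes were higher with 0 of 19 called and 4 adjusted over the list alone (camera adjusted p 2.04e-05, adjusted p = 0.213 with an estimated correlation). The chemokine gene XCL1 (2.24 ± 0.53, adjusted p = 0.309) passed with the block (0.0171). Immediate early genes were higher at a camera adjusted p of 7.07e-08 with a median of 0.47 (adjusted p = 0.213 with an estimated correlation). Cell cycle genes were lower at 4.20e-10 with a median of -0.70 (adjusted p = 0.314 with an estimated correlation), and the proliferation marker MKI67 was at -2.53 ± 0.69 (adjusted p = 0.459). MAIT and gamma-delta markers (7.61e-04, adjusted p = 0.490 with an estimated correlation), NF-kB genes (0.0379, adjusted p = 0.314) and effector transcription factors (0.0427, adjusted p = 0.364) were higher as lists, each with 0 genes called. Adjusted over the list alone, 1 of the MAIT and gamma-delta markers was called and 0 of the other lists named after the cytokines. With the block, genes called adjusted over the list alone were 10 higher for residency, 8 higher for NK-type receptors, 10 higher and 1 lower for cytokines, 8 higher for immediate early genes, 6 lower for the cell cycle, 5 higher for MAIT and gamma-delta markers, 2 higher for NF-kB and 1 higher for effector transcription factors. Of these, 2 NK-type receptor genes and 1 cytokine gene were called over all genes.

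Over all genes, 2 differed between CD69+ and CD69− cells in lymph node, at an adjusted p of 0.0456 each: GFI1, a zinc finger repressor (1.12 ± 0.14), and SLCO3A1, an organic anion transporter (-1.29 ± 0.16). At an unadjusted p under 0.05 there were 675. The block called 66, 25 higher and 41 lower, DESeq2 85 and limma voom 27. The count was 0 without any CD69− library, 0 without the CD69+ library of individual 2 or 3, and 3 without that of individual 1.

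The CD69 contrasts of the 2 tissues shared 1 call, SLCO3A1 (-1.27 ± 0.16 in bone marrow, chosen after its values were seen), against 0.00171 lower genes for independent lists. With the block they shared 41, 15 higher against 0.182 and 26 lower against 0.36. Across genes the fold changes had a Pearson r of 0.413 and a Spearman rho of 0.376. The CD69 effect differed between tissues for 0 genes in edgeR, DESeq2 and limma voom, with 204 at an unadjusted p under 0.05 in edgeR, for 1 gene with the block in edgeR and for 4 with the block in DESeq2. The lowest p-values belonged to CSF1 (lymph node effect minus bone marrow effect -1.47 ± 0.35), ATP10A (1.26 ± 0.33), C16orf45 (1.99 ± 0.52), CACNA2D2 (1.53 ± 0.45) and FANCD2 (-0.72 ± 0.19), all at an adjusted p of 1. The greater number of genes called in bone marrow was therefore not shown to be a difference between the tissues.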

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

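In this part the intervals over individuals, MALAT1, the share of small RNA counts from loci with their own promoter and the comparison of matched libraries were chosen only after the result was seen, and so was GZMB. Reads outside annotated genes, which no comparison uses, made up 55.0, 63.7, 71.5 and 75.8% of reads aligned to a single place in bone marrow CD69−, bone marrow CD69+, lymph node CD69− and lymph node CD69+ libraries (SD 4.25, 7.94, 1.67 and 5.55, n = 3), and the share was higher in lymph node in 6 of 6 matched pairs, by 5.32 to 19.4 percentage points.

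Per read on genes, the reads outside genes were 1.92 times higher in lymph node (95% interval over libraries 1.33 to 2.75). Genomic DNA would bring olfactory receptor genes, silent in T cells, up by as much, and their summed CPM over 386 genes was 7.13 ± 1.98 in bone marrow and 8.84 ± 2.93 in lymph node, a ratio of 1.23 (0.811 to 1.86). The interval over libraries ends below 1.92, but the libraries are paired by individual, and the interval over individuals (0.721 to 2.10) includes it, so the test leaves genomic DNA open. Unspliced RNA would raise counts at 1793 small nucleolar RNA and microRNA loci, most of them in introns, and their ratio was 1.03 (0.671 to 1.57, over individuals 0.337 to 3.13), but 52.7% of these counts came from loci with their own promoter, while MALAT1, a nuclear RNA, was higher in lymph node in 6 of 6 matched pairs, by 0.44 to 1.66 percentage points of counts, so nuclear RNA stays open. Strand-specific counting and tissue itself, the biological explanation the design gives, were not tested and stay open, and reads over introns and between genes, from the raw data, could settle the matter.

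The CD69 effect differed between tissues in the camera test, without an estimated correlation, for 10 lists. The fall in CD69+ cells was smaller in lymph node than in bone marrow for egress genes (adjusted p 0.0282, medians -1.68 and -2.02) and ribosomal protein genes (0.00122, -0.05 and -0.20), and steeper for cell cycle genes (0.00454, -0.70 and -0.37). The medians in lymph node and bone marrow were 0.05 and -0.72 for cytotoxic genes (0.00396), 0.91 and 0.07 for NK-type receptors (0.00612), 0.25 and -0.22 for effector transcription factors (0.00612) and 0.13 and 0.38 for follicular genes (0.0430). They were 0.27 and -0.01 for NF-kB genes (0.0430), 0.03 and -0.29 for Notch and Wnt genes (0.0138) and 0.12 and -0.16 for interferon-stimulated genes (0.00869). With an estimated correlation none of the 10 passed (adjusted p = 0.496 to 0.957). With the block egress genes (0.0902), follicular genes (0.0775) and Notch and Wnt genes (0.0646) did not pass, and oxidative phosphorylation genes did (0.0359, 0.101 without it, adjusted p = 0.289 with an estimated correlation as well). Without the block 0 genes of these lists were called for this difference, and with it 1 of the cytotoxic list was called (6 adjusted over the list alone) and 0 of the follicular list (1 lower). The highest of 100 draws of the group labels within individuals gave 14 genes for the difference between tissues, and since any draw reaches the real count of 0, as all 100 did, the draws say nothing for or against a difference.

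With the individual as a block, 1 gene differed between tissues in its CD69 effect: GZMB, a member of the cytotoxic list that encodes granzyme B, at 3.90 ± 0.41 (log2, SE, adjusted p = 0.0288), against 4.18 ± 1.66 (adjusted p = 1) without the block. Its level was 151 ± 200 CPM (SD) in bone marrow CD69−, 14.4 ± 16.6 in bone marrow CD69+, 31.4 ± 29.0 in lymph node CD69− and 55.8 ± 53.9 in lymph node CD69+ cells. It was higher in CD69+ cells in 0 of 3 individuals in bone marrow and in 3 of 3 in lymph node.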

How the results depend on the processing

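All genes called without the block were called with it as well, and of the genes named by rule and called, none turned its direction under an alternative chosen before the data were examined. Of those not called, 6 of 39 and 6 of 27 between tissues in CD69+ and CD69− cells and 22 of 126 and 26 of 115 by CD69 in lymph node and bone marrow turned under at least 1 alternative, 0, 2, 2 and 1 of them with the block, and 0 were called in the turned direction. Of the 97 named genes called between tissues in CD69+ cells, 66 lost the call under at least 1 of these alternatives, mostly a left-out library or individual, as did 75 of 110 in CD69− cells, 2 of 2 by CD69 in lymph node and 17 of 17 in bone marrow. Apart from the values printed in the report, the block ended no call of a named gene and added 19, 12, 7 and 17 among the named genes of these 4 comparisons. At 3 libraries per group and 4395877 to 14764446 counts, a gene absent from the calls is not shown to be unchanged. Counts that moved by more than 1.5 times follow, and the cause was not tested, except that fits with fewer libraries have fewer degrees of freedom.

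Between tissues in CD69+ cells, where 2346 genes were called, the count was 4701 with the block, 4789 with DESeq2 and the block, 1385 with only the 2 groups in the fit, and 445 to 2096 with a library or individual left out. In CD69− cells (3196) it was 5812 with the block, 5787 with DESeq2 and the block, and 958 to 2533 with leave-outs. Their overlap (1935) was 3934, 3980 and 416 to 639 in the same order. By CD69 in lymph node (2) it was 66 with the block, 85 with DESeq2, 259 with DESeq2 and the block, 27 with limma voom, 4 with upper-quartile factors, 6 with the stricter filter, 1 with only the 2 groups, and 0 to 3 with leave-outs. By CD69 in bone marrow (29) it was 225 with the block, 200 with DESeq2, 528 with DESeq2 and the block, 86 with limma voom, 0 with only the 2 groups, and 0 to 17 with leave-outs. The overlap of these (1) was 41, 43, 132 and 16 with the same 4 tools, 2 with RLE factors, 3 with upper-quartile factors, 2 with no filter, 4 with the stricter filter, and 0 with any individual left out. The difference between tissues (0) was 1 with the block and 4 with DESeq2 and the block. Of 43 list calls, 4 were kept with an estimated correlation, which made no other. The fry test called 25 lists, 21 of them among the 43, and the other settings called 43 to 53. By CD69, camera called 13 lists in bone marrow and 9 in lymph node. In each tissue fry called the egress list alone (adjusted p = 2.96e-04 in bone marrow and 0.0012 in lymph node).

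Some alternatives were chosen after seeing the data. With the share of reads outside genes as a covariate 661 genes were called in CD69+ and 614 in CD69− cells, and with the mean level of monocyte and granulocyte genes as a covariate 2 and 3. Tissue explained 62.3% and 93.9% of the variance of these 2 covariates, so the fit has little left to tell tissue from the second, and more from the first. Of the named calls, 45 of 97 and 37 of 110 were kept with the share and 0 of each with the monocyte and granulocyte level, where 18 and 25 had the opposite direction, none of them called, as 1 had with the share in CD69− cells. The named calls that the share ended went from a median absolute log2 fold change of 1.94 to 1.64 in CD69+ cells and from 2.09 to 1.54 in CD69− cells, with median SE 1.33 and 1.53 times as large, so part of these losses goes with smaller folds and part with wider errors. With the monocyte and granulocyte level the median absolute log2 fold changes of the named calls were 2.42 against 2.40 and 2.40 against 2.37, with median SE 2.71 and 2.89 times as large. These absolute values include the 18 and 25 genes that turned direction, so they do not show that the folds were kept. Without the 2 bone marrow libraries with the most haemoglobin, 1185 and 1963 genes were called between tissues and 0 by CD69 in bone marrow, and 69 of 97, 91 of 110 and 0 of 17 named calls were kept. The named calls lost went from a median absolute log2 fold change of 1.73 to 1.60, 2.06 to 1.79 and 2.29 to 1.99 in that order. Their median SE was 1.16, 1.09 and 1.15 times as large. By CD69 in bone marrow, leaving out all libraries of individual 1 or of individual 3 also gave 0.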

Other observations

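In this part the tests of heat shock genes and of the markers of other cells were chosen only after the result was seen, and so was the leaving out of libraries. HMGCS1, a gene of cholesterol synthesis, was higher in lymph node by 1.65 ± 0.27 (log2, SE) in CD69+ and 1.51 ± 0.27 in CD69− cells. The lipid list as a whole had 4 of 15 called higher and 2 lower in CD69+ cells (5 and 2 adjusted over the list alone) and 7 higher and 3 lower in CD69− cells (also 7 and 3), at camera adjusted p of 0.381 and 0.194. With the block the counts in CD69+ cells were 5 and 3 (6 and 4). The glucose transporter gene SLC2A3 rose by 1.30 ± 0.29 and 1.79 ± 0.29 and the glycolytic gene PGK1 by 1.00 ± 0.25 and 0.77 ± 0.25, in a list with 2 and 3 of 18 called higher (2 and 1 adjusted over the list alone, camera adjusted p 0.624 and 0.809). With the block that list had 3 higher and 3 lower in CD69+ cells and 3 higher and 5 lower in CD69− cells, with no change when adjusted over the list alone.

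Among interferon-stimulated genes, IFIT2 was lower in lymph node by 1.14 ± 0.29 in CD69+ and 1.44 ± 0.29 in CD69− cells, and IFIT3 by 2.10 ± 0.44 in CD69− cells, while MX2 was higher by 0.84 ± 0.21 and 0.79 ± 0.20. Among genes of T cell receptor signalling, the transcription factor NFATC1 rose by 1.38 ± 0.39 and 1.40 ± 0.39, and CD247, the zeta chain, fell by 0.68 ± 0.16 in CD69− cells. That list had 5 of 20 called higher and 0 lower in CD69+ cells, also 5 and 0 adjusted over the list alone, and 4 and 1 in CD69− cells (5 and 3 adjusted over the list alone), at camera adjusted p of 0.635 and 0.758. With the block the counts were 7 and 3 (7 and 6 adjusted over the list alone) in CD69+ and 7 and 6 (also 7 and 6) in CD69− cells. The cytokine gene TNFSF9 rose by 2.40 ± 0.28 and 2.11 ± 0.28, and IL16 fell by 1.35 ± 0.27 and 1.20 ± 0.27.

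The rise of immediate early and NF-kB genes in lymph node may come from the cells in the tissue or from their handling. After thinning all libraries to 4395877 counts, the median over 39 genes of the lists stayed at 0.999 times its value or more. At this equal depth the median was 1.757 in CD69+ and 1.685 in CD69− cells, against 1.76 and 1.67 before. Random thinning keeps the expected fold change of well-counted genes, so unequal counts alone are argued against as the cause for these genes. That outcome was therefore set in advance, and it says nothing on causes that go along with depth. With the share of reads outside genes as a covariate, the tissue term of the lists' mean level was 1.66 (log2, 95% interval over libraries 1.21 to 2.10), against 1.74 without it. The estimate thus moved little, and the share term was 0.006 per percentage point (-0.021 to 0.032). These values argue against the share as the whole cause for these lists. The intervals take the libraries as independent although they are paired by individual, and none over individuals was made. A part played by the share is therefore not excluded. A heat shock response would raise the 12 heat shock genes, whose median was 0.07 (bootstrap 95% interval -0.32 to 0.52) in CD69+ and 0.32 (-0.18 to 0.776) in CD69− cells, but 2 were called higher and 1 lower in CD69+ and 2 and 0 in CD69− cells (2 and 1 adjusted over the list alone in each, and 2 and 1 in each with the block), and a median over genes that go both ways decides nothing. Causes that go along with depth, a part played by the share of reads outside genes, a heat shock response, other handling and tissue itself therefore stay open. Cells fixed at collection could tell heat shock and other handling from tissue.

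The myeloid and erythroid transcripts of bone marrow libraries may come from RNA or cells of other types in those libraries. The 2 CD69 fractions of an individual deviated together from the bone marrow mean across 26 marker genes (lowest Spearman rho 0.949, highest 0.982). A change of the T cells of an individual would also give this, so it does not tell the source. If other cells are the source, genes that T cells share with myeloid cells, such as TYROBP and FCER1G, may differ between tissues through them. CD3E, CD8A and CD8B did not pass between tissues without the block. Single-cell counts from the same gates could tell other cells from a change of the T cells.

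When the 6 libraries of a comparison were divided into 3 and 3 in all 10 ways, only the real division, 1 of 10, gave as many genes for lymph node against bone marrow in CD69+ cells (2346), in CD69− cells (3196), and for CD69 in lymph node (2) and in bone marrow (29). The highest count of any other division was 0 in each. The block was fitted only for the 4 divisions that part the 2 libraries of every individual, where the highest of the others were 7, 2, 0 and 0, against 4701, 5812, 66 and 225 for the real one. With 10 divisions the share as high can never be under 0.05.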
